A study of Mus musculus with 4 samples.

How the data were processed

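Single-cell RNA was measured in 4 mouse tumour libraries, 2 labelled Control and 2 labelled Nanocapsule treated. The labels describe the tissue as tumour and the cells as cancer cells from C57Bl6 mice. They name neither the tumour line, the enzymes in the nanocapsules, nor which animals or days the libraries came from. The p-values of shares and single genes below therefore measure the spread between these 4 libraries.

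The authors deposited 1 unfiltered matrix of raw UMI (unique molecular identifier) counts per library, together with its droplet barcodes and gene names. Per the labels, libraries were made with the 10x Genomics single cell 3-prime v2 chemistry and aligned to mm10. The submitters' processing notes list Cell Ranger 2.1.1, whereas the matrix headers name Cell Ranger 4, so the version behind the counts is uncertain. Each matrix held 32285 genes, and 32235 of them were matched by Ensembl ID to release 21 of the mouse GENCODE annotation, which gave the GRCm38 coordinates of all 85 named genes. The 4 matrices held 688565, 628752, 668423 and 683582 barcodes for Control 1, Control 2, Nanocapsule 1 and Nanocapsule 2, most of them empty droplets.

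A barcode was called a cell when its total reached the order-of-magnitude rule, a fraction 1/10 of the 99th percentile of the 3000 largest barcodes, with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. The rule came to 8762, 14992, 11241 and 16256 UMIs in the same library order and left 7044 cells. A second set used at least 1500 UMIs in every library and held 9548 cells. This second minimum had been planned as an alternative. It was taken for the T-like and B-like cells, and as a second set for macrophage-like cells, after the data showed that the first rule left fewer than 20 T-like cells in every library. Scrublet, at an expected doublet rate of 0.06, marked 4 of the 7044 cells and 13 of the 9548. By a rule set before the data were examined, a caller that marks under 0.5% of over 5000 cells counts as not working, so no cell was left out as a doublet.

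Cells of all libraries were clustered together in scanpy 1.11.5 under Python 3.11.15, with numpy 2.4.6 and scipy 1.17.1. Counts were scaled to 10000 UMIs per cell and log-transformed. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, with no integration. Clusters were named from 20 marker sets fixed before the data were examined. The limits for a name were set afterwards: a median log2 fold of at least 3 over the other clusters with at least 3 markers at 5 CPM (counts scaled to a common total, as edgeR defines it), or for melanocytic tumour-like cells at least 2 over the clusters of other named classes. A cluster stayed unnamed when its 10 leading genes held more markers of another class, or when it was shallow and had no marker of its own among them.

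Shares of cells were compared with a two-sided exact permutation test of the difference between group means. With 2 libraries against 2 there are 6 splits, so the smallest p is 0.333 and this test cannot reach 0.05. The share of each library was given a 95% exact Clopper-Pearson interval. These intervals, and the limit of 3 counts for a count of 0, cover counting error only.

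For genes, UMIs were summed per library over all called cells and over each class with at least 20 cells in every library, since cells are not replicates. The sums were fitted in R 4.3.3 with edgeR 4.0.16 (TMM normalisation, filterByExpr, robust quasi-likelihood test) and Benjamini-Hochberg (BH) adjustment within each fit, at 0.05. Levels are given as TMM-normalised CPM, and log2 folds as nanocapsule over control. The standard error (SE) was derived as the absolute log2 fold divided by the square root of edgeR's F statistic. It does not show how few degrees of freedom 2 libraries per group leave, so a fold of many SE need not pass. Before the data were examined, 22 gene lists were fixed. They were tested with camera from limma 3.58.1 at its preset correlation of 0.01, with BH adjustment over the lists of a fit, and again with an estimated correlation. At the preset, members of a list count as nearly independent, so these p-values rest mostly on the number and spread of genes. They do not measure the spread of a list between libraries. Members of a list were also adjusted over the list alone. Counts of genes at an unadjusted p under 0.05 are given beside the adjusted calls, and a share of 0.05 is expected when no gene differs.

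Named genes followed a rule fixed before the data were examined. It takes the 10 largest rises and falls among genes past the threshold with at least 20 CPM and no overlap between groups, or, with fewer than 5 such genes, the 5 with the smallest unadjusted p. It adds up to 4 members of each list that passed, or the 2 most abundant if no member passed, and always Ldha, Cat and Hmox1. Other list members named below were chosen after their values were seen.

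The fits were tested on simulated data, with counts drawn at the trended dispersions of each fit and 200 genes changed. Genes of like level had the same dispersion there and no effect was shared between libraries, so recovery in the data may be lower. Of 100 genes changed 4-fold, edgeR recovered 89 in all called cells, 94 in tumour-like, 84 in macrophage-like, 70 in T-like and 66 in B-like cells. Of 100 genes changed 2-fold it recovered 62, 70, 20, 11 and 13 in the same order. A list shifted 2-fold passed camera at the preset correlation in each fit. With an estimated correlation its camera adjusted p lay between 0.0299 and 0.206, and it passed in all called cells alone. The estimated correlation thus had little power in the simulation. Genes were drawn independently there, so a pass at the preset correlation was built in and does not test that preset. In the data the estimated correlation in tumour-like cells was 0.916 for the interferon gamma list and 0.802 for the MHC class I list.

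The alternatives tried were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, the replicate number as a block and each library left out in turn. Others were a mitochondrial limit of 10%, the 1500 UMI minimum, Leiden resolution 2.0, subtraction of the profile of barcodes with at most 50 UMIs at 10% of each sum, thinned sums and equal weight per class. Alternatives chosen after seeing the data were a minimum of 500 UMIs, tumour-like cells without UMIs of immune genes, crossed numbers as a block in T-like cells, and the ambient and thinned sums for gene lists. With fewer than 3 libraries per group, other splits of the libraries and a test for a library far from its group were not run.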

Results

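The series title names enzyme nanocapsules, T cell immunity and cancer immunotherapy, and its design compares tumours with and without nanoparticle treatment. Gene expression was measured by droplet single-cell RNA sequencing in 2 Control libraries and 2 Nanocapsule libraries, so n = 2 per group throughout. The libraries held 140491491 UMIs in Control 1, 98943390 in Control 2, 108441772 in Nanocapsule 1 and 105967866 in Nanocapsule 2. In the same order, 3255, 1100, 1613 and 1076 cells were called, with medians of 38034, 78300, 59190 and 85275 UMIs per cell.

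The share of cell classes addresses whether treated tumours held more immune cells, T cells in particular. Most called cells were melanocytic tumour-like, that is, they carried pigment cell transcripts such as Dct, Pmel and Mlana. Their share was 90.4% ± 7.78 (SD, n = 2) in control and 87.3% ± 3.70 in nanocapsule libraries. Immune cells, mostly macrophage-like, made up 2.57% ± 1.77 of control and 4.94% ± 2.34 of nanocapsule cells. Among immune cells, the T-like share was 4.68% ± 3.25 in control and 17.2% ± 5.60 in nanocapsule libraries, from 3 of 43 and 1 of 42 immune cells against 7 of 53 and 15 of 71. Macrophage-like cells made up the rest, 95.3% ± 3.25 and 82.8% ± 5.60.

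Both immune class shares differed without overlap between the groups (two-sided exact permutation p = 0.333, the smallest this test can give with 2 against 2). The tumour-like and total immune shares overlapped between groups (exact permutation p = 0.667 for each). Without Control 2 the log2 ratio of the immune shares was 1.90 against 0.94 with all libraries, and without Control 1 that of the T-like shares was 2.85 against 1.88. Fibroblast-like cells were lower in the nanocapsule libraries without overlap, at 0.58% ± 0.05 against 0.31% ± 0.09 (exact permutation p = 0.333). Endothelial-like cells were rare in both groups, at 0.18% ± 0.13 and 0.12% ± 0.09 (exact permutation p = 0.667). Cells left unnamed were 6.26% ± 5.94 and 7.34% ± 1.18 (exact permutation p = 1.0), and included a cluster led by Fgf21 and a shallow cluster with few mitochondrial UMIs.

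At a minimum of 1500 UMIs, which keeps smaller cells, the T-like share of immune cells was 8.51% in Control 1, with a 95% Clopper-Pearson interval of 5.28 to 12.8. It was 23.4% in Control 2 (19 to 28.2), 24.9% in Nanocapsule 1 (19.1 to 31.4) and 27.6% in Nanocapsule 2 (22 to 33.8). The group means were 15.9% ± 10.5 and 26.2% ± 1.94 (exact permutation p = 0.333). Control 2 thus lay within the intervals of both nanocapsule libraries, and the log2 ratio of means was 0.72 against 1.88 by the first rule. At Leiden resolution 2.0, where NK cells formed their own cluster, the T share of immune cells was 5.91%, 19.38%, 19.37% and 21.4% in the same order, and the groups overlapped. Macrophage-like cells made up 54.5% ± 8.91 and 48.0% ± 2.49 of immune cells at this minimum, B-like cells 16.9% ± 5.65 and 15.1% ± 8.91, and a dendritic cluster named plasmacytoid 12.6% ± 4.04 and 10.6% ± 4.49. That cluster was mixed, led also by Cd209a, Ccl22 and Mgl2, and at resolution 2.0 it gave way to 84 conventional and 34 plasmacytoid dendritic cells. Plasmacytoid cells then made up 4.09%, 4.92%, 2.09% and 2.18% of immune cells in the same order, and conventional ones 6.36%, 11.1%, 5.76% and 10.04%. With the clusters of resolution 1.0, the total immune share at this minimum was 12.4% ± 8.81 in control and 11.96% ± 4.52 in nanocapsule libraries, a log2 ratio of -0.047 against 0.94 by the first rule.

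**Figure D1:**
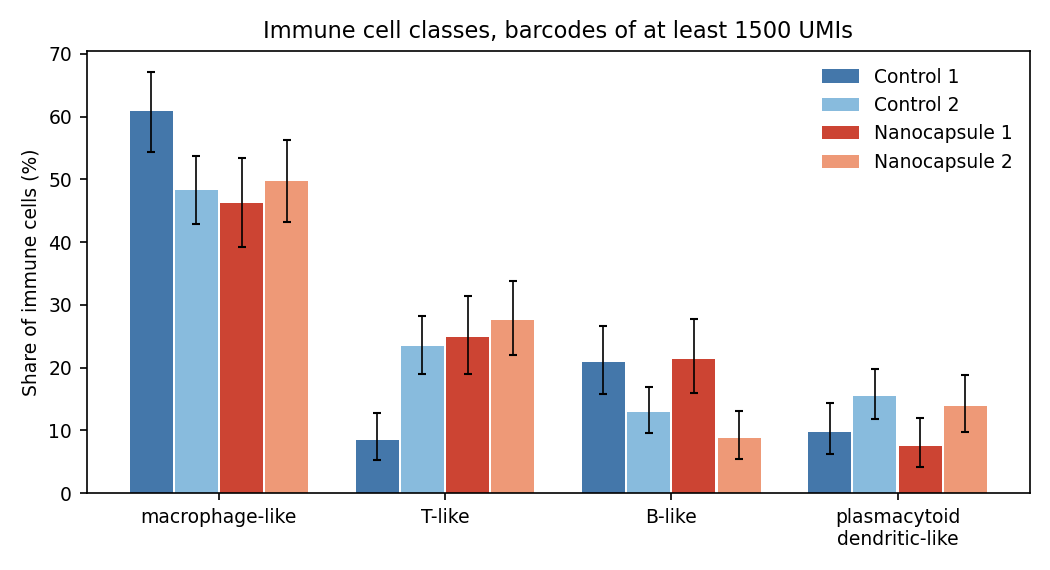
Share of immune cells (y axis, %) for 4 immune classes (x axis) in each library, among barcodes of at least 1500 UMIs; bars are shares and error bars 95% Clopper-Pearson intervals, which cover counting error only. The T-like share was 8.51% in Control 1 and between 23.4% and 27.6% in the other 3 libraries.

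Summed over all called cells, the comparison asks what differed among cells past the first rule. That rule, at 8762 to 16256 UMIs, left out most immune cells kept at 1500 UMIs, so the sums do not cover the tumour as a whole. Of the genes of MHC class I presentation and the interferon gamma response, 15 of 16 and 18 of 19 were higher in both nanocapsule libraries than in both controls. This held for fewer of the type I interferon (9 of 21), MHC class II (5 of 10), cytotoxic (12 of 17) and inflammatory macrophage genes (10 of 15). Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, had 66.7 and 63.3 CPM in Control 1 and 2 against 154 and 176 in Nanocapsule 1 and 2 (log2 fold 1.34 ± 0.09 SE). B2m, the light chain of MHC class I molecules, went from 225 and 226 CPM to 490 and 573 (1.24 ± 0.10), and Arg1, the arginine-degrading arginase 1, from 1.59 and 1.12 CPM to 11.1 and 16.9 (3.35 ± 0.29). Isg20, an interferon-induced exonuclease (0.93 ± 0.09), and Vgll3, a transcription cofactor (0.65 ± 0.07), completed the 5 genes with the smallest p. Ldha, a subunit of lactate dehydrogenase, and Cat, catalase, barely differed, at log2 folds of -0.028 ± 0.195 and -0.038 ± 0.075.

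None of the 16937 genes tested in all called cells passed edgeR with BH adjustment, the smallest adjusted p being 0.376 for Hmox1. At an unadjusted p under 0.05, 726 genes were higher and 614 lower, the DESeq2 Wald test called 169, and edgeR called 1, 1, 67 and 4 without Control 1, Control 2, Nanocapsule 1 and Nanocapsule 2. With the replicate number as a block edgeR called 548 genes, though no label says that the numbers pair the libraries. The 2 groups did not overlap for 39% of genes, against 33.3% by chance.

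Class shares moved with these sums: T-like cells were 0.09% ± 0.0 of control and 0.91% ± 0.68 of nanocapsule cells (log2 ratio 3.32), macrophage-like cells 2.48% ± 1.77 and 4.03% ± 1.66 (0.70), and fibroblast-like cells 0.58% and 0.31% (-0.90). The T-like share rests on 3, 1, 7 and 15 cells, against 20, 80, 50 and 66 T-like cells at 1500 UMIs. The sums of all cells were also fitted at 1500 UMIs, but the lists of that fit are not given here. Whether the UMI minimum of the first rule moved the T cell lists was therefore not weighed. At 1500 UMIs the groups overlapped for T-like cells (2.43% ± 2.71 and 3.18% ± 1.42, log2 ratio 0.39) and macrophage-like cells (6.35% ± 3.71 and 5.80% ± 2.47, -0.13). Of the 17 measured cytotoxic effector genes, 16 were higher, and 9 passed when adjusted over the list alone, among them Gzmb at 0.40 and 0.59 CPM against 2.91 and 6.39, and Nkg7 at 0.36 and 0.17 against 2.41 and 11.3. The list rose in camera with BH adjustment (median log2 fold 2.17, adjusted p = 2.37e-20; adjusted p = 0.265 with an estimated correlation). All 15 inflammatory macrophage genes were higher, 8 passed over the list alone, including Nos2 and Acod1, and the list rose (median 1.65, camera BH adjusted p = 9.48e-21; adjusted p = 0.265 with an estimated correlation). Without Nanocapsule 2 these medians fell to 1.26 and 1.07. The naive and memory T cell list (9 of 11 higher, 5 over the list alone, median 0.48) and the regulatory T cell list (8 of 8 higher, 4 over the list alone, median 0.66) rose as well, at camera BH adjusted p = 1.17e-05 and 3.45e-07. With an estimated correlation their adjusted p = 0.265 and adjusted p = 0.361. Without Nanocapsule 2 the medians were 0.24 and 0.24. Without Nanocapsule 1 and Control 2 the regulatory median was 1.00 and 1.48. Without Control 1 the regulatory list no longer passed (camera BH adjusted p = 0.0802).

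The T cell exhaustion and checkpoint list rose too (12 of 16 higher, 5 over the list alone, median 0.93, camera BH adjusted p = 6.26e-06; adjusted p = 0.375 with an estimated correlation). Without Control 1 (adjusted p = 0.209, median 0.61) it did not pass. Without Nanocapsule 2 its median was 0.43. In the alternatively activated macrophage list Arg1 alone passed over the list (median 0.35, camera BH adjusted p = 3.29e-05; adjusted p = 0.265 with an estimated correlation). That list failed without Control 1 (median 0.069, adjusted p = 0.126), its median was -0.05 without Nanocapsule 2, and it was 1.11 without Control 2 and 1.04 without Nanocapsule 1. Extracellular matrix genes fell (4 of 18 higher, none over the list alone, median -0.44, camera BH adjusted p = 0.000159; adjusted p = 0.265 with an estimated correlation), with a median of -0.27 without Nanocapsule 1. The angiogenesis and endothelial activation list did not pass (7 of 13 higher, median 0.036, camera BH adjusted p = 0.241; adjusted p = 0.505 with an estimated correlation), except without Control 2 (median 0.52, adjusted p = 0.0167). The lists of tumour-like cells, which supplied most UMIs, are given with that class.

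In melanocytic tumour-like cells, 934 to 3122 per library with 78208350 to 126338674 UMIs, the comparison asks how the cancer cells themselves differed. Antigen presentation and interferon gamma response genes were higher in both nanocapsule libraries. B2m was at 214 and 204 CPM in Control 1 and 2 against 458 and 537 in Nanocapsule 1 and 2 (log2 fold 1.25 ± 0.10 SE), and H2-D1, a classical MHC class I heavy chain, at 62.5 and 54.2 against 111 and 142 (1.11 ± 0.14). Hmox1 was at 61.8 and 53.9 CPM against 128 and 129 (1.15 ± 0.09). Ldha (-0.036 ± 0.180) and Cat (-0.031 ± 0.080) lay within the spread between libraries, at 3108 and 2206 against 2714 and 2469 CPM and at 27.0 and 29.6 against 26.9 and 28.5 CPM.

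Of 19 interferon gamma response genes, all were higher and 17 passed when adjusted over the list alone. Gbp2, a guanylate-binding protein, was at 0.76 and 1.40 CPM against 8.46 and 43.9 (4.63 ± 0.94), and Irgm1, an immunity-related GTPase, at 4.92 and 6.88 against 14.04 and 46.2 (2.36 ± 0.60). The list rose in camera with BH adjustment (median log2 fold 3.08, adjusted p = 3.15e-42; adjusted p = 0.448 with an estimated correlation). All 15 MHC class I presentation genes were higher, 14 passed over the list alone, and the list rose (median 1.14, camera BH adjusted p = 3.3e-62; adjusted p = 0.448 with an estimated correlation). They included Tap2, a subunit of the peptide transporter, at 1.18 and 1.11 CPM against 5.32 and 9.56 (2.70 ± 0.31), and the immunoproteasome subunit Psmb8 at 0.71 and 1.56 against 8.88 and 29.6. Both lists share Nlrc5, Psmb9 and Tap1.

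The change was uneven between cells. With each tumour-like cell thinned to 8000 UMIs, cells held a mean of 4.12, 3.96, 7.57 and 9.87 MHC class I list UMIs in Control 1, Control 2, Nanocapsule 1 and Nanocapsule 2, and medians of 4, 3, 5 and 5. A cluster of tumour-like cells led by Prph, Irgm1, Igtp and Tgtp2 held 17, 11, 42 and 128 cells, or 0.54%, 1.18%, 2.90% and 14.1% of the class, and 17.4%, 43.0%, 49.6% and 84.4% of its interferon gamma list UMIs. Outside that cluster, which was drawn from the same genes, the interferon gamma list was at 16.4, 18.9, 45.5 and 63.4 CPM and the MHC class I list at 497.5, 462, 845.4 and 779.3. Interferon gamma list UMIs were absent from 87.7%, 84.9%, 74.6% and 62.2% of thinned cells. UMIs of the immune marker genes Ptprc, Cd3e, Cd3d, Cd3g, Lyz2, C1qa, C1qb, C1qc, Tyrobp, Fcer1g and Cd74 were found in 24.7%, 39.0%, 38.2% and 51.2% of unthinned tumour-like cells, shares that overlap between the groups, at median depths of 38657, 82589, 61673 and 90287 UMIs. Per UMI counted they were higher in both nanocapsule libraries, at 18.5, 17.0, 26.7 and 59.0 CPM. Cd74 is also a member of the MHC class II list given below for these cells, so these UMIs need not come from immune RNA alone.

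MHC class II genes rose as a list, with 8 of 8 higher and Ctss, Ciita and H2-DMb1 past the threshold over the list alone (median 2.61, camera BH adjusted p = 2.93e-14; adjusted p = 0.448 with an estimated correlation). H2-DMb1 had 2.97 and 2.34 CPM against 7.29 and 7.38 (1.46 ± 0.15), whereas Cd74, at 4.73 and 0.92 against 5.76 and 29.4, was high in Nanocapsule 2; without that library the list's median was 1.05, and without Control 1 it was 3.96. The type I interferon list rose (20 of 20 higher, none over the list alone, median 0.72, camera BH adjusted p = 1.06e-08; adjusted p = 0.561 with an estimated correlation). Without Control 1 (median 0.29, adjusted p = 0.366) it did not pass. Its median was 0.20 without Nanocapsule 2 and 1.56 without Control 2. Chemokines rose (10 of 10 higher, Ccl8 over the list alone, median 1.33, camera BH adjusted p = 2.23e-07; adjusted p = 0.534 with an estimated correlation). Without Control 2 (median 0.88, adjusted p = 0.209) it did not pass. The median was 0.29 without Nanocapsule 2 and 2.09 without Control 1.

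Lists of macrophage genes moved the same way in melanocytic tumour-like cells. Inflammatory macrophage genes rose (8 of 8 higher, none over the list alone, median 1.04, camera BH adjusted p = 3.43e-05; adjusted p = 0.448 with an estimated correlation), with medians of 2.59, 1.74 and 0.10 without Control 1, Nanocapsule 1 and Nanocapsule 2. Alternatively activated macrophage genes rose too (6 of 8 higher, none over the list alone, median 0.95, camera BH adjusted p = 0.00237; adjusted p = 0.448 with an estimated correlation), with medians of 0.056 and 0.43 without Control 1 and Nanocapsule 2. Among tumour-like cells with no immune UMI, 3 genes of the second list could be tested and 0 were higher (median -0.096, camera BH adjusted p = 0.609).

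Hypoxia response genes passed camera (18 of 20 higher, none over the list alone, median 0.28, BH adjusted p = 9.9e-05; adjusted p = 0.586 with an estimated correlation). The median was -0.071 without Control 2, where the call was lost and the direction turned (adjusted p = 0.424), 0.14 without Nanocapsule 1 (adjusted p = 0.355) and 0.83 without Control 1. Fam162a, for example, was at 1171, 580, 1118 and 789 CPM in Control 1, Control 2, Nanocapsule 1 and Nanocapsule 2. In the oxidative stress list, which passed (13 of 23 higher, median 0.056, camera BH adjusted p = 0.00428; adjusted p = 0.448 with an estimated correlation), Hmox1 alone passed over the list alone, and the list's call was lost without Nanocapsule 2 (median 0.026, adjusted p = 0.0611).

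Oxidative phosphorylation, proliferation and p53 lists fell in camera by small amounts, with 7 of 27, 6 of 22 and 3 of 12 members higher and none past the threshold over the list alone. Their medians were -0.075, -0.10 and -0.10, at camera BH adjusted p = 0.0148, 0.00428 and 0.0121; with an estimated correlation their adjusted p = 0.586, adjusted p = 0.574 and adjusted p = 0.561. Leaving out Control 1 (median -0.011), Nanocapsule 1 (-0.080) or Nanocapsule 2 (-0.060) ended the call for oxidative phosphorylation, whose median was -0.14 without Control 2. Leaving out Control 2 (-0.047) or Nanocapsule 1 (-0.034) ended it for proliferation, whose median was -0.16 without Nanocapsule 2. Leaving out Control 1 (-0.017) or Nanocapsule 2 (-0.069) ended it for p53, whose median was -0.27 without Control 2 and -0.20 without Nanocapsule 1. Glycolysis (15 of 19 higher, Ldhb lower over the list alone), pigmentation (7 of 15), unfolded protein response (9 of 15) and dissociation genes (6 of 16) did not pass (camera BH adjusted p = 0.204, 0.1, 0.12 and 0.113; with an estimated correlation adjusted p = 0.715, adjusted p = 0.586, adjusted p = 0.561 and adjusted p = 0.561). The glycolysis list passed in opposite directions without Control 1 (median 0.32, adjusted p = 6.39e-11) and without Control 2 (median -0.15, adjusted p = 0.00817). Unfolded protein genes passed without Control 1 (median 0.29, adjusted p = 0.000221) or Nanocapsule 1 (0.20, adjusted p = 0.0478). Pigmentation genes did without Control 2 (-0.12, adjusted p = 0.00268) or Nanocapsule 1 (-0.065, adjusted p = 0.0478), and dissociation genes without Control 2 (-0.16, adjusted p = 0.0148) or Nanocapsule 2 (-0.084, adjusted p = 0.000575).

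None of the 16242 genes tested in tumour-like cells passed edgeR with BH adjustment. The smallest adjusted p was 0.177, for Hmox1 and B2m, followed by Vgll3 (0.69 ± 0.07), H2-DMb1 and Tap2. At an unadjusted p under 0.05 there were 1225 genes, the DESeq2 Wald test called 91, and edgeR called 54, 0, 72 and 27 without Control 1, Control 2, Nanocapsule 1 and Nanocapsule 2. With the replicate number as a block, a pairing that no label gives, edgeR called 192 genes. Groups did not overlap for 38.6% of genes, against 33.3% by chance.

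**Figure D2:**
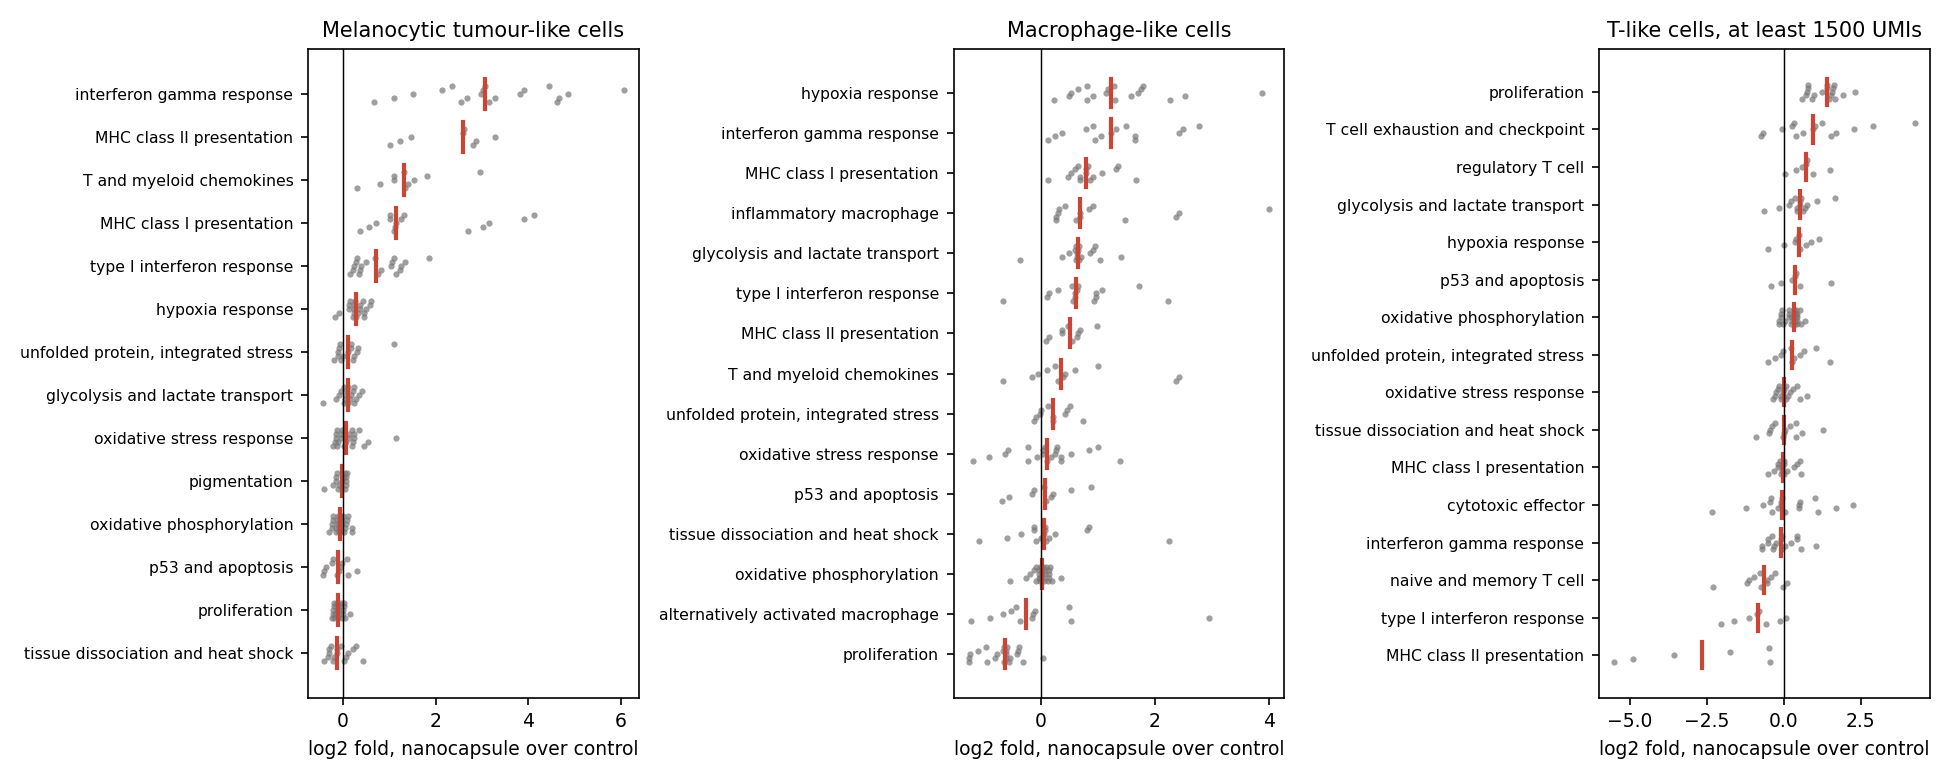
Log2 fold of nanocapsule over control (x axis) for each measured member (grey points) of the gene lists (y axis) in 3 cell classes; red bars are list medians. In tumour-like cells the interferon gamma list had a median of 3.08, in macrophage-like cells the hypoxia list 1.24, and in T-like cells the proliferation list 1.40.

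In macrophage-like cells, 40 to 56 per library with 551943 to 1585461 UMIs, Arg1 and hypoxia response genes were higher in the nanocapsule libraries. Arg1 was at 188 and 101 CPM in Control 1 and 2 against 1299 and 919 in Nanocapsule 1 and 2 (log2 fold 2.95 ± 0.34 SE). Ndrg1, a gene induced by hypoxia, was at 46.1 and 47.1 against 370 and 177 (2.53 ± 0.39), and Hcar2, a receptor for hydroxycarboxylic acids, at 7.38 and 4.71 against 59.3 and 57.0 (3.29 ± 0.39). Cxcl3, a neutrophil-attracting chemokine, was at 14.8 and 1.18 against 117 and 98.6 (3.97 ± 0.63). Syngr1, a vesicle membrane protein, was lower, at 279 and 266 against 82.8 and 99.8 (-1.57 ± 0.22). Hmox1 was at 941 and 328 against 1630 and 1690 CPM (1.39 ± 0.45).

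All 18 hypoxia response genes were higher, 7 of them past the threshold over the list alone, including Vegfa, Bnip3 and Egln3. The list rose in camera with BH adjustment (median 1.24, adjusted p = 5.03e-17; adjusted p = 0.446 with an estimated correlation), with a median of 0.39 without Nanocapsule 1. All 16 MHC class I genes were higher, 13 over the list alone, and the list rose (median 0.80, camera BH adjusted p = 2.38e-16; adjusted p = 0.333 with an estimated correlation). Of these, H2-Q7 was at 35.1 and 24.7 CPM against 105 and 83.8, and B2m at 2340 and 2085 against 4224 and 2938. The inflammatory macrophage list rose (14 of 14 higher, Nos2 and Acod1 over the list alone, median 0.69, camera BH adjusted p = 8.42e-09; adjusted p = 0.333 with an estimated correlation). Nos2, the inducible nitric oxide synthase, was at 7.38 and 0 CPM against 70.4 and 32.6.

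The glycolysis list rose (16 of 17 higher, none over the list alone, median 0.66, camera BH adjusted p = 9.9e-10; adjusted p = 0.446 with an estimated correlation), with Ldha at 1593 and 903 CPM against 2387 and 1462. Its median was 1.07 without Control 1 and 0.42 without Control 2. The interferon gamma list rose (15 of 15 higher, Cd274 over the list alone, median 1.23, camera BH adjusted p = 9.9e-10; adjusted p = 0.446 with an estimated correlation). Without Nanocapsule 2 (median 0.34, adjusted p = 0.0721) it did not pass. The median was 2.04 without Control 1. The MHC class II list rose (10 of 10 higher, none over the list alone, median 0.52, camera BH adjusted p = 0.000297; adjusted p = 0.469 with an estimated correlation). Without Nanocapsule 2 (median 0.13, adjusted p = 0.632) it did not pass. The median was 0.85 without Nanocapsule 1. The type I interferon list rose (15 of 16 higher, Ifit2 over the list alone, median 0.62, camera BH adjusted p = 1.88e-07; adjusted p = 0.446 with an estimated correlation), with medians of 0.23 and 0.94 without Nanocapsule 1 and Nanocapsule 2.

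Proliferation genes fell (1 of 22 higher, none over the list alone, median -0.63, camera BH adjusted p = 4.41e-08; adjusted p = 0.469 with an estimated correlation). Without Nanocapsule 1 (median -0.25, adjusted p = 0.159) it did not pass. The median was -1.73 without Nanocapsule 2. Chemokines passed at a camera BH adjusted p = 0.0379 (9 of 12 higher, median 0.35; adjusted p = 0.595 with an estimated correlation). Their median was -0.14 without Control 2 (adjusted p = 0.869), -0.049 without Nanocapsule 2 (adjusted p = 0.895), 1.47 without Control 1 and 0.76 without Nanocapsule 1. The alternatively activated list did not pass as a whole (3 of 12 higher, median -0.25, camera BH adjusted p = 0.375; adjusted p = 0.717 with an estimated correlation), with medians of -0.45 without Control 1 and -0.02 without Control 2. Over the list alone Arg1 was higher, while the lipid carrier Apoe, at 4924 and 6482 against 3050 and 1845 CPM, and Gas6 were lower. Oxidative stress, oxidative phosphorylation, unfolded protein, p53 and dissociation lists did not pass (camera BH adjusted p = 0.375, 0.889, 0.083, 0.793 and 0.627; with an estimated correlation adjusted p from 0.595 to 0.955). Cytotoxic effector genes passed in macrophage-like cells (5 of 6 higher, median 0.62, camera BH adjusted p = 0.00317; adjusted p = 0.446 with an estimated correlation), with a median of 0.28 without Nanocapsule 1. Unfolded protein genes passed without Nanocapsule 2 (median 0.30, adjusted p = 0.0491) and dissociation genes without Control 2 (median 0.32, adjusted p = 0.00759).

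None of the 7526 genes tested in macrophage-like cells passed edgeR with BH adjustment, the smallest adjusted p being 0.18 for Arg1 and Hcar2. At an unadjusted p under 0.05 there were 356, DESeq2 called 8, and edgeR called 15, 0, 29 and 68 without Control 1, Control 2, Nanocapsule 1 and Nanocapsule 2. Groups did not overlap for 33.1% of genes, against 33.3% by chance.

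At the 1500 UMI minimum, 93 to 165 macrophage-like cells per library were compared. Arg1 was at 272 and 253 CPM against 1179 and 772 (1.89 ± 0.26), Nos2 at 9.84 and 12.2 against 66.6 and 35.8 (2.17 ± 0.39), Cd274, the checkpoint ligand PD-L1, at 64.7 and 80.0 against 229 and 164 (1.43 ± 0.25), and Hmox1 at 721 and 546 against 1636 and 1311 (1.22 ± 0.24). Fcrls (-2.26 ± 0.43) and Saa3 (-3.38 ± 0.64) were lower. Over their lists alone, Arg1, Nos2, Cd274 and Hmox1 each passed. None of 9610 genes passed edgeR with BH adjustment (smallest adjusted p = 1), 204 had an unadjusted p under 0.05, and DESeq2 called 1. Groups did not overlap for 27.5% of genes, against 33.3% by chance.

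The hypoxia list rose at the 1500 UMI minimum as well, by less (19 of 19 higher, median 0.38, camera BH adjusted p = 3.39e-07; adjusted p = 0.591 with an estimated correlation). Its call was lost without Control 2 (median 0.13, adjusted p = 0.543) or Nanocapsule 1 (median 0.057, adjusted p = 0.494), and the median was 1.09 without Control 1 and 0.75 without Nanocapsule 2. The MHC class I list rose (16 of 16 higher, none over the list alone, median 0.42, camera BH adjusted p = 4.58e-07; adjusted p = 0.591 with an estimated correlation). Without Control 1 (median 0.25, adjusted p = 0.208) or Nanocapsule 2 (median 0.17, adjusted p = 0.0994) it did not pass. The median was 0.70 and 0.69 without Control 2 and Nanocapsule 1. The MHC class II list rose (8 of 9 higher, median 0.63, camera BH adjusted p = 1.46e-06; adjusted p = 0.591 with an estimated correlation), with a median of 0.26 without Nanocapsule 2. The type I interferon list had the opposite sign to that by the first rule (3 of 19 higher, median -0.20, camera BH adjusted p = 0.0391; adjusted p = 0.769 with an estimated correlation). Leaving out Control 2 turned its median to 0.35 (adjusted p = 0.00262). Without Nanocapsule 1 the list did not pass (median -0.24, adjusted p = 0.0593), and the median was -0.63 without Control 1 and -0.40 without Nanocapsule 2.

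The interferon gamma list rose in macrophage-like cells at 1500 UMIs (19 of 19 higher, Cd274 over the list alone, median 0.82, camera BH adjusted p = 3.11e-08; adjusted p = 0.591 with an estimated correlation). Its median was -0.46 without Nanocapsule 2 (adjusted p = 0.103) and 1.40 without Nanocapsule 1. Glycolysis genes rose (16 of 19 higher, median 0.34, camera BH adjusted p = 6.01e-05; adjusted p = 0.627 with an estimated correlation). Without Control 2 (median 0.030, adjusted p = 0.918) or Nanocapsule 1 (0.021, adjusted p = 0.371) it did not pass. The median was 0.70 without Control 1 and 0.55 without Nanocapsule 2. Inflammatory genes rose (9 of 14 higher, median 0.20, camera BH adjusted p = 0.000119; adjusted p = 0.591 with an estimated correlation). Without Control 1 (-0.11, adjusted p = 0.73) or Nanocapsule 2 (0.21, adjusted p = 0.0994) it did not pass. The median was 0.64 without Control 2 and 0.49 without Nanocapsule 1. Proliferation genes fell (6 of 22 higher, median -0.23, camera BH adjusted p = 1.51e-05; adjusted p = 0.591 with an estimated correlation). Without Control 2 (-0.30, adjusted p = 0.0725) or Nanocapsule 1 (0.024, adjusted p = 0.77) it did not pass. The median was -0.38 without Control 1 and -0.73 without Nanocapsule 2.

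At that minimum the alternatively activated list fell although Arg1 was higher (5 of 15 higher, median -0.31, camera BH adjusted p = 0.0391; adjusted p = 0.591 with an estimated correlation). It passed without Control 1 (-0.56, adjusted p = 0.0087), but not without Control 2 (-0.095, adjusted p = 0.239), Nanocapsule 1 (-0.28, adjusted p = 0.376) or Nanocapsule 2 (-0.43, adjusted p = 0.228). Unfolded protein genes rose (12 of 15 higher, median 0.12, camera BH adjusted p = 0.0251; adjusted p = 0.627 with an estimated correlation). Without Control 2 (0.043, adjusted p = 0.853) or Nanocapsule 1 (0.077, adjusted p = 0.439) it did not pass. The median was 0.25 without Control 1 and 0.22 without Nanocapsule 2. Chemokines rose (6 of 10 higher, median 0.26, camera BH adjusted p = 0.0166; adjusted p = 0.591 with an estimated correlation). Without Control 1 (0.11, adjusted p = 0.213), Control 2 (0.20, adjusted p = 0.511) or Nanocapsule 2 (-0.13, adjusted p = 0.389) it did not pass. The median was 0.42 without Nanocapsule 1. Pigmentation genes passed in macrophage-like cells at 1500 UMIs (11 of 15 higher, median 0.26, camera BH adjusted p = 0.0321; adjusted p = 0.769 with an estimated correlation). Their median was 1.06 without Control 1, -0.34 without Control 2 (adjusted p = 0.00488) and 0.006 without Nanocapsule 1 (adjusted p = 0.77). Oxidative stress (12 of 22 higher), oxidative phosphorylation (17 of 27), p53 (7 of 14) and dissociation genes (6 of 17) did not pass, at camera BH adjusted p = 0.671, 0.947, 0.947 and 0.262; with an estimated correlation adjusted p from 0.629 to 0.96. Oxidative phosphorylation and p53 genes had a median and a mean of opposite signs, 0.026 and -0.004 and -0.003 and 0.018, and oxidative stress genes passed without Nanocapsule 2 (median 0.23, adjusted p = 0.0137).

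**Figure D3:**
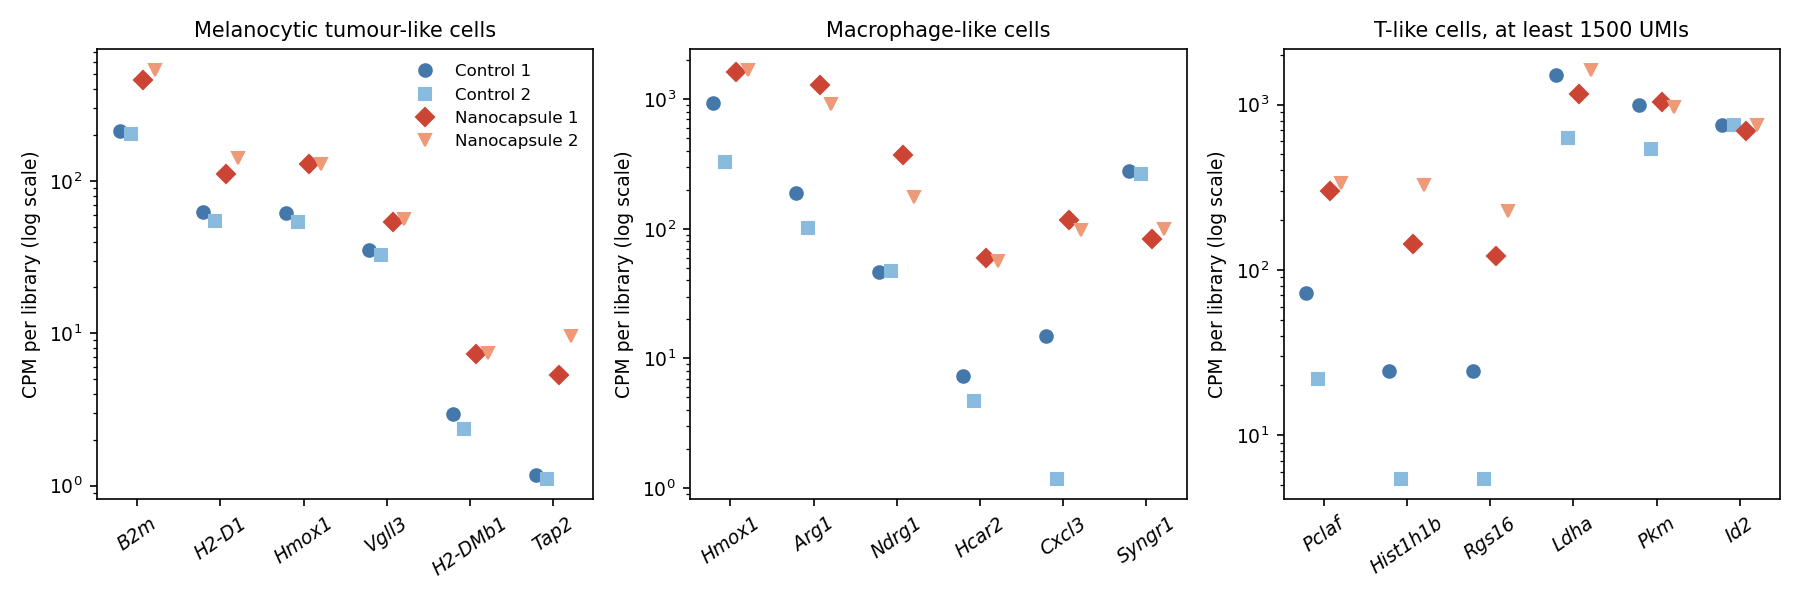
Level of 6 genes (x axis) in CPM on a log scale (y axis) for each library in tumour-like, macrophage-like and T-like cells; each point is 1 library. In macrophage-like cells Arg1 lay at 188 and 101 CPM in the controls against 1299 and 919 in the nanocapsule libraries, and in T-like cells Rgs16 at 24.3 and 5.45 against 121 and 228. The T-like sums of Control 1 and 2 held 86111 and 390798 UMIs, so Rgs16 rests on a few UMIs in each control.

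T-like cells, 20 in Control 1, 80 in Control 2, 50 in Nanocapsule 1 and 66 in Nanocapsule 2, address the T cell immunity that the title names. At Leiden resolution 2.0, 7, 17, 13 and 17 of them fell in a cluster named natural killer (NK) cells, so values of the class, the Cd4, Cd8 and Foxp3 shares included, cover T and NK cells. Genes of exhaustion and checkpoints were higher in the nanocapsule libraries. Rgs16, a regulator of G protein signalling in that list, was at 24.3 and 5.45 CPM in Control 1 and 2 against 121 and 228 in Nanocapsule 1 and 2 (log2 fold 4.25 ± 0.64 SE). The checkpoint receptor genes Havcr2 (36.4 and 5.45 against 62.0 and 105 CPM, 2.88 ± 0.68), Lag3 (48.6 and 35.4 against 88.1 and 272, 2.29 ± 0.59), Pdcd1 (85.0 and 62.7 against 124 and 305, 1.69 ± 0.48) and Tigit (97.2 and 76.3 against 196 and 276, 1.54 ± 0.34) followed. Genes of dividing cells led the smallest p. The replication factor Pclaf was at 72.9 and 21.8 against 300 and 336 CPM (3.23 ± 0.46). The linker histone gene Hist1h1b was at 24.3 and 5.45 against 144 and 327 CPM (4.67 ± 0.70). The sums of Control 1 and 2 held 86111 and 390798 UMIs, so the control levels of Rgs16, Havcr2 and Hist1h1b rest on a few UMIs each.

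Of 15 exhaustion and checkpoint genes in T-like cells, 12 were higher and 7 passed over the list alone. The list rose in camera with BH adjustment (median 0.94, adjusted p = 1.99e-07; adjusted p = 0.54 with an estimated correlation), with a median of 0.50 without Nanocapsule 2. In sums thinned to the smallest library the call was lost (6 of 10 higher, median 0.18, camera BH adjusted p = 0.102). The same thinning ended the call of the proliferation list given next (6 of 6 higher, median 0.60, adjusted p = 0.102). All 18 proliferation genes were higher, none over the list alone (median 1.40, camera BH adjusted p = 5.04e-07; adjusted p = 0.54 with an estimated correlation). This rested on Control 2, where Mki67 was at 19.1 CPM against 255 in Control 1, 137 in Nanocapsule 1 and 187 in Nanocapsule 2. Without Control 2 the proliferation median was 0.038 and the direction turned (adjusted p = 0.538), without Control 1 it was 2.74 and without Nanocapsule 2 it was 0.67. The regulatory T cell list rose (7 of 7 higher, Tnfrsf4 over the list alone, median 0.72, camera BH adjusted p = 0.000698; adjusted p = 0.54 with an estimated correlation). Without Control 2 (median 1.52, adjusted p = 0.0501) it did not pass.

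The cytotoxic effector list did not pass in T-like cells (8 of 18 higher, median -0.075, mean 0.094, camera BH adjusted p = 0.389; adjusted p = 0.826 with an estimated correlation). Within it, Ifng, at 109 and 92.7 CPM against 242 and 384 (1.69 ± 0.35), and Ccl4 were higher over the list alone, and the list passed without Control 1 (median 0.34, adjusted p = 0.00379) or Nanocapsule 2 (median 0.064, adjusted p = 0.022). Glycolysis (13 of 15 higher, median 0.51) and oxidative phosphorylation genes (21 of 27, median 0.32) rose, at camera BH adjusted p = 0.000917 and 0.00663; with an estimated correlation their adjusted p = 0.54 and adjusted p = 0.549. Both calls were lost without Control 2 (medians 0.21 and 0.14, adjusted p = 0.347 and 0.389), and that of oxidative phosphorylation also without Nanocapsule 2 (median 0.14, adjusted p = 0.203), while the glycolysis median was 0.90 without Control 1.

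The falls of 3 lists in T-like cells, MHC class II, type I interferon and naive and memory, also rested on Control 2. MHC class II genes (0 of 6 higher, 3 over the list alone, median -2.66, camera BH adjusted p = 2.11e-05; adjusted p = 0.54 with an estimated correlation) were high in that library, with H2-Aa at 36.4, 526, 6.53 and 7.30 CPM in Control 1, Control 2, Nanocapsule 1 and Nanocapsule 2. Leaving out Control 2 left a median of -0.13 (adjusted p = 0.538). Type I interferon genes (1 of 8 higher, Isg15, Irf7 and Rtp4 over the list alone, median -0.85, camera BH adjusted p = 0.00388; adjusted p = 0.54 with an estimated correlation) had a median of 0.25 without Control 2 (adjusted p = 0.389), and of -1.91, -1.41 and -1.84 without Control 1, Nanocapsule 1 and Nanocapsule 2. Naive and memory genes (1 of 12 higher, median -0.64, camera BH adjusted p = 0.0034; adjusted p = 0.549 with an estimated correlation) had medians of 0.21 without Control 2 (adjusted p = 0.931), -0.11 without Nanocapsule 2 (adjusted p = 0.882) and -1.23 without Nanocapsule 1. Pigment cell transcripts were higher in the T-like cells of both controls, with Tyrp1 at 121 and 60.0 against 16.3 and 14.6 CPM and Dct at 60.7 and 70.9 against 16.3 and 14.6. As a list, pigmentation genes had the smallest p of the fit to T-like cells at 1500 UMIs (0 of 5 higher, 4 over the list alone, median -2.15, camera BH adjusted p = 2.81e-09; adjusted p = 0.428 with an estimated correlation). Without Control 2 their median was -1.68 (adjusted p = 5.65e-05). These other lists did not pass: hypoxia, oxidative stress, unfolded protein, p53, dissociation, interferon gamma and MHC class I (camera BH adjusted p = 0.0572, 0.746, 0.0777, 0.0759, 0.806, 0.541 and 0.746; with an estimated correlation adjusted p from 0.54 to 0.905). The last pair had medians of -0.11 and -0.032 but an upward camera statistic. Some of these passed with 1 library left out. Interferon gamma did without Control 2 (median 0.82, adjusted p = 0.00024), and hypoxia without Control 1 (0.44, adjusted p = 0.0345) or Nanocapsule 2 (0.84, adjusted p = 9.18e-06). Unfolded protein genes did without Control 1 (0.32, adjusted p = 0.0345) or Nanocapsule 2 (0.36, adjusted p = 0.0219), and p53 (0.65, adjusted p = 0.0271) and dissociation (0.41, adjusted p = 4.11e-06) without Nanocapsule 2.

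None of the 5577 genes tested in T-like cells passed edgeR with BH adjustment, the smallest adjusted p being 0.116 for Pclaf, Hist1h1b and Rgs16. At an unadjusted p under 0.05 there were 426, DESeq2 called 3, and edgeR called 33, 3, 52 and 3 without Control 1, Control 2, Nanocapsule 1 and Nanocapsule 2. Groups did not overlap for 36% of genes, against 33.3% by chance. Penk, the enkephalin precursor, had 1 UMI in control and 60 in nanocapsule T-like cells, a ratio of 27.2 with a 95% counting interval of 4.70 to 1090, and the histone gene Hist1h2ap had 1 and 57 (25.8, 4.45 to 1040). These intervals treat UMIs as independent and do not cover the spread between cells or libraries. The depth of these sums was low, at 86111, 390798, 338113 and 725674 UMIs, with medians of 3000, 4238, 4884 and 6851 UMIs per cell.

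Among T-like cells, a UMI of Cd8a or Cd8b1 was found in 32.5% ± 10.6 of control and 45.8% ± 8.10 of nanocapsule cells (exact permutation p = 0.667). Cd4 was found in 16.9% ± 16.8 and 11.5% ± 3.50, and Foxp3, the regulatory T cell factor, in 6.90% ± 4.40 and 7.80% ± 0.30 (exact permutation p = 1.0 for each). With each cell thinned to 1000 UMIs, the shares were 26.9% and 34.9% for Cd8a or Cd8b1, 8.10% and 2.80% for Cd4, and 5.60% and 2.50% for Foxp3 (exact permutation p = 0.667, 0.333 and 1.0). B-like cells, which should lack these genes, showed a UMI of them in 0 of 157 cells. This allows up to 6.12%, 6.82%, 6.98% and 14.3% of the cells of Control 1, Control 2, Nanocapsule 1 and Nanocapsule 2. Their median was 2586 UMIs, against 5008 in T-like cells. The Cd4 share was 28.8% in Control 2, and without that library the log2 ratio of the Cd4 shares was 1.21; without Control 1 that of Foxp3 was 1.05.

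In B-like cells, 21 to 49 per library with 69815 to 127580 UMIs, edgeR with BH adjustment called 3 of 1955 genes, all lower in the nanocapsule libraries and all immunoglobulin kappa variable genes. Igkv5-43 had 77 UMIs in control and 0 in nanocapsule cells, at least 22.1-fold lower against a limit of 3 counts over the group (adjusted p = 5.73e-05). Igkv6-15 had 71 and 1, a ratio of 0.0163 with a 95% counting interval of 0.000408 to 0.094 (adjusted p = 0.00424), and Igkv3-7 had 32 and 0, at least 9.20-fold lower (adjusted p = 0.0336). Igkv5-43 in B-like cells at 1500 UMIs did not pass when 500 UMIs were the minimum (edgeR BH adjusted p = 0.859). Igkv6-15 in B-like cells at 1500 UMIs did not pass in DESeq2 (BH adjusted p = 0.0592) or thinned sums (0.152), nor Igkv3-7 in B-like cells at 1500 UMIs in DESeq2 (0.143) or with the ambient profile subtracted (0.0573). These UMIs came from 1 to 4 cells per control library, for Igkv5-43 from 1 of 49 in Control 1 and 4 of 44 in Control 2, as a rearranged kappa gene belongs to single B cells and their clones. All 46 Igkv6-15 UMIs of Control 1 and all 25 of Control 2 came from 1 cell each. The bounds and the interval above treat UMIs as independent, so they set no limit on the fold counted in cells. DESeq2 called 1 gene, 95 had an unadjusted p under 0.05, and edgeR called 11, 8, 12 and 29 genes without Control 1, Control 2, Nanocapsule 1 and Nanocapsule 2; Igkv3-7 did not pass without Control 1 (adjusted p = 0.571) or Control 2 (adjusted p = 0.983). Groups did not overlap for 34% of genes, against 33.3% by chance.

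No gene list passed in B-like cells. MHC class II genes had 0 of 10 members higher (median -0.16) and MHC class I genes 5 of 13 (median -0.041), at camera BH adjusted p = 0.525 and 0.741; with an estimated correlation adjusted p = 0.9 and adjusted p = 0.922. Without Nanocapsule 1 dissociation genes passed (median -0.72, adjusted p = 0.000739), and without Control 2 glycolysis genes did (-0.58, adjusted p = 0.0138). Over their lists alone, Herpud1 (1.33 ± 0.42) was higher and Fosb (-1.30 ± 0.33) lower. Ldha (0.028 ± 0.401) and Cat (0.019 ± 0.428) differed by less than their errors.

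On GRCm38, Hmox1 (ENSMUSG00000005413) lies on chromosome 8 from 75093621 to 75100589, B2m (ENSMUSG00000060802) on chromosome 2 from 122147686 to 122153083, and Arg1 (ENSMUSG00000019987) on chromosome 10 from 24915221 to 24927484. H2-D1 (ENSMUSG00000073411) lies on chromosome 17 from 35262730 to 35267499, Tap2 (ENSMUSG00000024339) on chromosome 17 from 34203527 to 34216321, and Gbp2 (ENSMUSG00000028270) on chromosome 3 from 142620602 to 142638008. Ndrg1 (ENSMUSG00000005125) lies on chromosome 15 from 66929318 to 66969640, Rgs16 (ENSMUSG00000026475) on chromosome 1 from 153740349 to 153745468, and Pclaf (ENSMUSG00000040204) on chromosome 9 from 65890237 to 65903266. The annotation lists these 9 as protein-coding, and Igkv5-43 (ENSMUSG00000094433), on chromosome 6 from 69823355 to 69823943, as an immunoglobulin variable gene.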

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

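Of the 4 tests of the first pattern, those of depth per cell and of the level of immune markers were chosen after the result was seen, the marker measure being changed once after its first value, as was the use of the fit without Nanocapsule 2, itself planned, as a test.

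In near-empty droplets, barcodes of at most 50 UMIs that no comparison used, RNA of the interferon gamma and MHC class I lists was above both controls in both nanocapsule libraries. For the interferon gamma list the levels were 47.0 and 65.4 CPM in Control 1 and 2 against 120.7 and 404.5 in Nanocapsule 1 and 2, so the lowest nanocapsule library was 1.85 times the highest control. For the MHC class I list they were 486.6 and 614.4 against 925 and 1152 CPM, a ratio of 1.51. Both lists also rose in tumour-like cells in camera, as did MHC class II, which was not above both controls in these droplets (a ratio of 0.52); for each of the 3 the adjusted p = 0.448 with an estimated correlation.

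Without the tumour-like cells that held a UMI of an immune gene, the MHC class I median was 0.79 against 1.14, which decides nothing about RNA of immune cells, since free RNA falls on all cells alike and the result set beforehand to speak against it was wrongly chosen. The immune genes also included Cd74, a member of the MHC class II list, so this step can remove tumour-like cells in which that list rose. Immune RNA as the whole source is argued against by marker levels: by the median marker of each of the 4 immune classes at 1500 UMIs, it could carry at most 14.4% of either list's rise in tumour-like cells. A sum over the markers, run first, gave up to 114%, through the plasmacytoid markers Bst2 and Tcf4, at 87.8 and 109 and at 52.4 and 59.4 CPM in tumour-like cells of the controls, whereas Siglech was at 0.12 and 0. Nanocapsule 2 alone was argued against by an interferon gamma median of 2.14 without it, against 3.08. Depth per cell was argued against by Control 2, which was deeper than Nanocapsule 1 (medians 82589 and 61673 UMIs). In thinned cells the lowest nanocapsule mean of MHC class I UMIs exceeded the highest control mean by 3.45. That gap decides nothing about depth, since thinning keeps a gene's expected level. A response of tumour cells to interferon in treated animals may explain the pattern, as a hypothesis untested here, and animals or handling that differed between the libraries stay open because the labels do not give them.

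The remaining results of this part were not weighed. Among barcodes of at least 500 UMIs, 84 of Nanocapsule 1 were erythroid-like, against 5 in Control 1, 5 in Control 2 and 2 in Nanocapsule 2.

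Some lists went opposite ways in pairs of classes, with every nanocapsule library on 1 side of both controls in each class; the difference was not tested for any pair. For the mean log2 level of the same members, MHC class II genes differed by 3.48 between tumour-like and T-like cells (1.40 against -2.08), by 2.56 between macrophage-like and T-like cells (0.48 against -2.08), and by 2.58 with macrophage-like cells at 1500 UMIs. The T-like value rested on Control 2, without which the median of that list was -0.13. MHC class I genes differed by 0.93 between macrophage-like and B-like cells (0.81 against -0.11), and by 0.56 with macrophage-like cells at 1500 UMIs. Oxidative phosphorylation genes differed by -0.31 between tumour-like and T-like cells (-0.060 against 0.25), a pair whose lists each lost their call with 1 library left out: without Control 1 the tumour-like median was -0.011, and without Control 2 the T-like median was 0.14.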

How the results depend on the processing

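The alternatives at 500 UMIs, the tumour-like cells without immune UMIs, the crossed numbers, and the ambient and thinned sums for lists were chosen after the data were seen. Leaving out 1 library was planned for genes, lists and class shares, and added later for the Cd4, Cd8 and Foxp3 shares. DESeq2 size factors changed none of the 90 list calls. They, the subtracted ambient profile and a mitochondrial limit of 10% each left the 6 gene counts within 1.5 times of those reported. Over all alternatives, list results kept their direction and side of the threshold in 617 cases, lost the call in 118, gained it in 29, reversed in 12 and moved in 43. For named genes these were 1625, 7, 147, 0 and 101. No alternative moved the median log2 fold of all genes by over 0.1. Where a value changed, the cause was not tested unless stated.

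Counts of genes past the threshold are given for all called, tumour-like, macrophage-like, macrophage-like at 1500 UMIs, T-like and B-like cells, against 0, 0, 0, 0, 0 and 3 in edgeR, which had 1340, 1225, 356, 204, 426 and 95 genes at an unadjusted p under 0.05. In macrophage-like cells by either rule and in B-like cells, the unadjusted counts were under a share of 0.05 of the genes tested. Without a filter on low counts the counts past the threshold were 2, 7, 107, 39, 58 and 20, and by the DESeq2 Wald test 169, 91, 8, 1, 3 and 1. With the replicate number as a block they were 548, 192, 3, 0, 3 and 8, of which DESeq2 shared 124, 59, 3, 0, 1 and 1. The numbers are not taken as pairs, since no label says so; libraries of the same number correlated at 0.644, 0.614, 0.186, 0.192, -0.107 and 0.06 over 1955 to 6517 genes, and crossed numbers as a block gave 0 genes in T-like cells (256 at an unadjusted p under 0.05). In tumour-like cells with no immune UMI the count was 1. At 500 UMIs it was 15 in T-like and 6 in B-like cells, and in thinned sums 1 and 1. Leaving out 1 library, where the lone library is assumed to vary like the others, gave 1 to 67, 0 to 72, 0 to 68, 0 to 1, 3 to 52 and 8 to 29.

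With an estimated correlation in camera, medians stayed as they were by construction and the BH adjusted p was 0.586 for hypoxia (0.277), 0.448 for interferon gamma (3.076) and 0.448 for MHC class I (1.142) in tumour-like cells. It was 0.446 for hypoxia (1.241) and 0.333 for MHC class I (0.801) in macrophage-like cells, and 0.54 for exhaustion (0.939) and 0.54 for proliferation (1.397) in T-like cells. In T-like sums thinned to the smallest library, exhaustion had a median of 0.175 and proliferation 0.596, each at a BH adjusted p = 0.102 in camera. For exhaustion fewer members were tested there, and over the same members the median was 0.861 against 0.905.

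With 1 library left out, hypoxia in tumour-like cells ranged from -0.071 to 0.826 and T-like proliferation from 0.038 to 2.743. Other lists that reversed without 1 library were, in all called cells, glycolysis (-0.16 to 0.335) and hypoxia (-0.059 to 0.862), in tumour-like cells glycolysis (-0.146 to 0.322), and in macrophage-like cells chemokines (-0.142 to 1.473). In macrophage-like cells at 1500 UMIs these were type I interferon (-0.627 to 0.345), interferon gamma (-0.463 to 1.402), unfolded protein (0.043 to 0.254) and chemokines (-0.125 to 0.422), and in T-like cells type I interferon (-1.911 to 0.249) and naive and memory (-1.231 to 0.209). Where a range stays above 0, camera's direction turned while the median did not.

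For shares, the log2 ratio at 1500 UMIs was -0.047 for immune cells and 0.718 for T-like cells of immune cells. At 500 UMIs it was -0.255 for tumour-like, -0.173 for immune, 0.006 for macrophage-like of immune and 0.712 for T-like of immune cells. With 1 library left out it ranged from 0.355 to 1.903 for the immune share, 1.299 to 2.85 for the T-like share, -1.316 to 1.207 for Cd4 and -0.361 to 1.054 for Foxp3, which was -1.161 in thinned cells. For the T cell share of immune cells, the edgeR fit to cell counts gave 1.862 at an unadjusted p of 0.0281, and 0.111 with the replicate block.

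No doublets were removed, so keeping them was not run as an alternative, and T-like genes at Leiden resolution 2.0 were not run because a library had fewer than 20 cells. In simulated data 11, 13 and 20 of 100 genes changed 2-fold were recovered in T-like, B-like and macrophage-like cells. Neither depth nor the dispersion of genes of like level was varied there.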

Other observations

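The test of NK cells in the T-like class was set before its result was seen, and the fits without 1 library or at 1500 UMIs had been planned. Their use as tests of these patterns came after the results were seen, as did the tests of pigment genes, thinned sums and tumour RNA in T-like cells.

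In macrophage-like cells, the hypoxia list and Arg1 were higher in nanocapsule libraries (list median 1.24). RNA of tumour cells is argued against by the pigment genes Tyrp1, Gpnmb, Mitf, Pmel, Dct and Mlana, whose median there was -0.027. At 1500 UMIs the pigmentation list had a median of 0.26 beside 0.38 for hypoxia, so for that smaller rise tumour RNA stays open. A single library stays open for the size of the list's rise, since without Nanocapsule 1 the median was 0.39. The high UMI minimum of the first cell rule stays open as well, for the same value at 1500 UMIs, and so does an effect of the treatment, as untested.

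In T-like cells, exhaustion and proliferation lists were higher in nanocapsule libraries (medians 0.94 and 1.40). For exhaustion, the median was 0.71 in the clusters named T at Leiden resolution 2.0, against 0.91 in the class, with a pseudocount of 5 CPM. Those clusters held 13 cells and 54477 UMIs in Control 1, under the minimum of 20 cells. The value therefore argues only weakly against NK cells in the class. In thinned sums the list lost its call (median 0.18 over the 10 members tested, camera BH adjusted p = 0.102), and a median of 0.86 after thinning over the same members decides nothing, since thinning keeps a gene's expected level, so depth per cell, which separated the groups, stays open. A single library as the whole source is argued against by the medians with 1 library left out. The lowest was 0.50, without Nanocapsule 2, against 0.94. Nanocapsule 2 stays open for the size of the list's rise, and a camera call cannot settle it, since camera does not measure the spread between libraries. Less RNA of tumour cells, at 3.85%, 2.46%, 1.01% and 0.97% of T-like UMIs by pigment genes, is argued against by the rise of at most 0.043 it would give. For proliferation, Control 2 alone could carry the pattern, since the median was 0.038 without it, while for exhaustion an effect of the treatment, or of the animals, stays open as untested.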
